A study of Danio rerio with 3 samples.

How the data were processed

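Poly(A) RNA from the intestine of adult zebrafish (Danio rerio) was sequenced in paired reads of 150 bases, with 1 library for each of 3 diets, per the labels. The groups were taken from the treatment label of each sample: commercial feed (Tetramin, a commercial fish feed) as control, and feeds of which 50% was the fruit pulp of Cavendish or of Fe'i bananas, with the same commercial feed as the rest. Feeding lasted 8 weeks at 4% of body weight a day, and intestines were taken on day 56 after 24 hours without food. How many fish, and of which sex, went into each library is not given in the sources used here, nor is the part of the intestine taken.

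Reads were checked with FastQC 0.11.5 and aligned with TopHat2 2.1.0, and the genome build was GRCz11, per the submitters' processing notes. The deposited values are FPKM (fragments per kilobase of transcript, relative to all mapped fragments) from Cufflinks, per the file headers, each with a 95% confidence interval and a status. The version and options of Cufflinks are not given in the sources used here. The interval covers counting and the assignment of reads to genes within a library, not differences between fish. Each file holds 32661 rows for 32519 gene identifiers; 117 identifiers own 259 rows, which were summed. In every library 9 rows, all within the vitellogenin cluster of chromosome 22, carry the Cufflinks status for too many fragments and are listed at 0, so they were left out. Gene symbols are those paired with the identifiers in the files, and 89.8% of the identifiers are also in the gene name table used here.

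FPKM carry no read totals, so depth was read from the deposited intervals. The interval is the FPKM plus or minus 2 SD, and the squared ratio of FPKM to SD gives an effective number of fragments per gene. Among genes with fewer than 20 effective fragments this number came out whole, within 0.05, for 44.6% in the control, 44.2% in the Cavendish and 44.4% in the Fe'i library. The whole numbers (tolerance 0.01) gave a relative depth of 1.27 for the Cavendish and 0.816 for the Fe'i library, with the control library at 1. Because fewer than 50% of low genes came out whole, no count test was run. A median measured gene had 147, 180 and 115 effective fragments in the control, Cavendish and Fe'i libraries. PCR copies are not independent molecules, so the intervals may understate counting error, and they do not cover differences between fish.

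Each library was divided by a scaling factor, the median ratio to the geometric mean over genes at 1 FPKM or more in all 3 libraries (1.06 for the control, 0.969 for the Cavendish and 0.965 for the Fe'i library). This keeps a few abundant transcripts from moving all other genes. Ratios are differences of log2(scaled FPKM + 1), which understates the change of low genes, and folds are these ratios put back on a linear scale. With 1 library per diet there is no replicate check of any difference and no p-value was computed. A gene was called higher or lower between 2 libraries when its log2 ratio was at least 1 in size, the higher library was at 1 FPKM or more, the status was OK and the scaled 95% intervals did not overlap. There were 14067 genes at 1 FPKM or more in at least 1 library. Values after ± are scaled half-widths of the deposited 95% interval, and a counting SE is the error these intervals give to a log2 ratio.

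There were 36 gene lists, covering nutrient handling, cell types of the gut wall, neighbouring organs, immune and stress responses, the cell cycle and the clock. Of their 1330 symbols, 1250 matched the files. Each list is given by its calls and its median log2 ratio, with the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Some lists share genes, at most 4 between any pair. Genes named in the text are the 10 with the highest and the 10 with the lowest ratio among called genes at 5 FPKM or more with a gene name, up to 4 members per list with the ratios of greatest size at 5 FPKM or more, and 14 fixed genes of carotenoid and retinoid handling, whatever their values. Outside this rule the text names rarga and cyp26b1, set for a test before their values were looked at, and mbl2, ptf1a and vtg2, chosen after their values were seen. The groups, lists, rules and alternative settings were fixed before the data were examined. Members of near-identical families (elastases and trypsins, zona pellucida proteins, galectins, chemokines, C-reactive proteins, immunoglobulin and T cell receptor segments) share reads and their values are uncertain.

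The rule was tested on simulated data for the Cavendish against control comparison, with counting error only, over 14067 genes. It called 74 of 100 genes changed 3-fold, 90 of 100 changed 6-fold and 28 of 13867 unchanged genes. A simulated list of 30 genes raised 1.5-fold had a median above all random lists, and an unchanged list of 30 lay at percentile 37.5. Calls shared by both banana diets were set against 100 simulated pairs of unchanged libraries with 1 shared control, once with counting error only and once with a spread between libraries estimated from Fe'i against Cavendish, which includes any effect of the kind of banana.

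Alternatives were the FPKM as deposited, scaling every library to the same sum (TPM), the same without exocrine pancreas and mitochondrially encoded genes, a pseudocount of 0.1 or 5, no minimum or a minimum of 5 FPKM, no condition on intervals, identifiers with repeated rows left out, and a log2 ratio of 2. A further one, without the genes of the lists for pancreas, liver, gonad, muscle, fibroblasts and erythrocytes, was added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.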

Results

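RNA from the zebrafish intestine was profiled after 8 weeks on a commercial control feed, on a feed with Cavendish banana, the pale dessert fruit, or on a feed with Fe'i banana, whose orange pulp is rich in carotenoids. Each diet has 1 library, so the errors given with values are errors of counting and read assignment within a library. The relative depths of the control, Cavendish and Fe'i libraries were 1, 1.27 and 0.816, and a median measured gene rested on 147, 180 and 115 effective fragments. They held 12486, 12944 and 12581 genes at 1 deposited FPKM or more. The libraries also differed in transcripts of neighbouring organs. Exocrine pancreas genes took 6.53% of all FPKM in the control, 15.4% in the Cavendish and 5.62% in the Fe'i library. Liver genes took 0.857%, 1.18% and 2.6%, and mitochondrially encoded genes 12.0%, 10.9% and 17.4%. The liver share is too low by an unknown amount, since vitellogenin genes of the liver list are among the rows listed at 0. The mitochondrial share leans heavily on 1 short gene, mt-atp8, at 48215 ± 5402, 60590 ± 6585 and 90817 ± 9158 scaled FPKM in the control, Cavendish and Fe'i libraries.

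The first comparison asks what the Cavendish diet did to intestinal transcripts. Genes of cholesterol synthesis, of inflammation, of the pancreas and of smooth muscle and connective tissue were higher in the Cavendish library than in the control library. Genes that pack dietary lipid into lipoproteins were lower more often than higher. Among called genes with a gene name, the lowest ratio belonged to cyp26a1 (ENSDARG00000033999, chromosome 12, 8954761 to 8958353 in GRCz11), which encodes an enzyme that breaks down retinoic acid. It stood at 74.0 ± 4.37 FPKM in the control and 1.2 ± 0.401 in the Cavendish library, 34.2-fold lower (log2 ratio -5.09, counting SE 0.14). In all, 799 genes were called higher and 232 lower.

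Of 29 measured genes of cholesterol synthesis and uptake, 18 were called higher in the Cavendish library and 0 lower, with a median log2 ratio of 1.15, above all 10000 random lists. hmgcra (chromosome 5, 50972485 to 50992775), the rate-limiting enzyme of the pathway, was at 19.3 ± 1.3 FPKM in the control and 93.9 ± 4.34 in the Cavendish library, a 4.68-fold difference. cyp51, which demethylates lanosterol, was at 50.8 ± 3.03 and 196 ± 8.99 FPKM, and msmo1, a later step, at 145 ± 4.68 and 434 ± 7.65. srebf2, the transcription factor that drives these genes, was 2.72-fold higher. This library also held more pancreatic RNA (exocrine list median 1.57) and more liver RNA (liver list median 0.84). The cell types behind the cholesterol genes were not resolved.

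**Figure D1:**
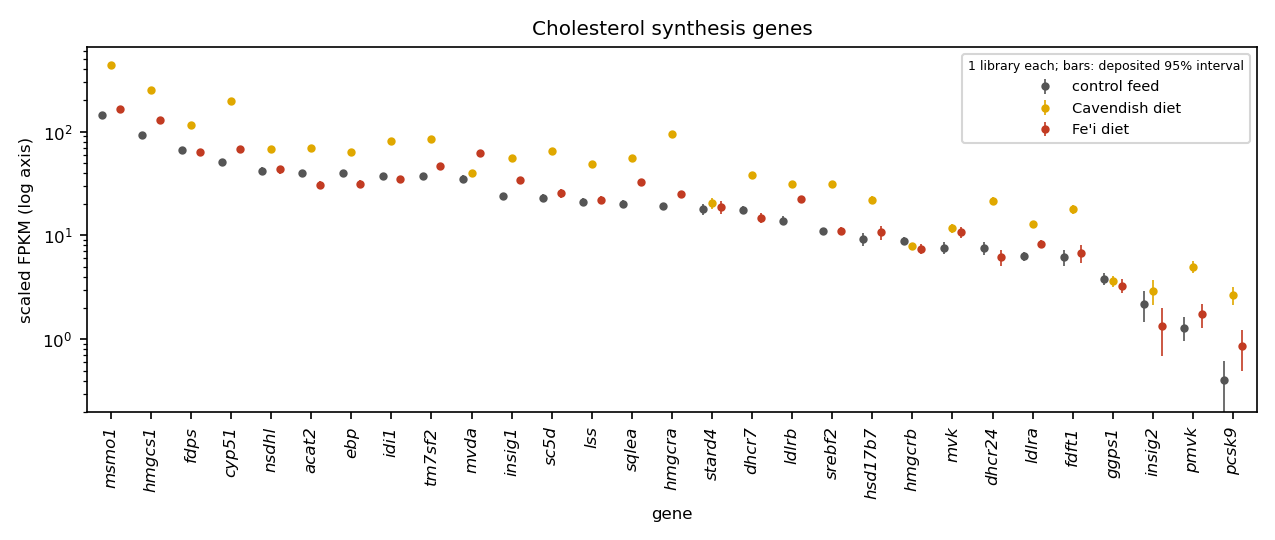
Scaled FPKM (log axis) of the 29 measured genes of the cholesterol synthesis list in the control, Cavendish and Fe'i libraries, 1 library each, ordered by their level in the control library; bars are the deposited 95% intervals. Against the control library 18 genes were called higher in the Cavendish library and 0 in the Fe'i library.

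Among 39 genes of lipid absorption and lipoproteins, 5 were called higher and 8 lower in the Cavendish library, with a median of -0.51, below all random lists. apoa4a (chromosome 19, 10845953 to 10850834), an apolipoprotein of the lipoprotein particles made by enterocytes, was at 709 ± 32.3 FPKM in the control and 106 ± 6.58 in the Cavendish library. apoeb, apolipoprotein E, was at 1559 ± 48.8 and 499.8 ± 18.7, while apobb.2 was 4.14-fold higher. Fatty acid synthesis genes had a median of 0.46 (0.21 to 0.51 over the alternatives, percentile 99.99), with 3 of 21 called higher and 1 lower. thrsp, a regulator of lipogenesis, was at 0.236 ± 0.472 and 35.9 ± 5.55 FPKM, and me1, malic enzyme, went the other way, from 50.1 ± 3.22 in the control to 8.47 ± 1.02 in the Cavendish library. Fatty acid oxidation genes had 1 of 31 called higher and 0 lower, at a median of -0.20 (percentile 7.03).

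For sugar metabolism, 5 of 34 uptake and glycolysis genes were called higher and 1 lower, with a median of 0.17 (percentile 97.7) that turned to -0.04 under TPM scaling. gck, glucokinase, was 12.6-fold higher, at 27 ± 1.84 FPKM against 1.23 ± 0.365. It is known from liver and pancreatic islets, whose marker lists were also higher in this library. Of 13 gluconeogenesis genes, 0 were called, with a median of -0.19 (percentile 8.91), and pck1, its first committed enzyme, was at 473 ± 20.3 and 258 ± 11.3 FPKM. Of 18 bile acid genes, 5 were called higher and 1 lower (median 0.40, 0.18 to 0.49 over the alternatives, percentile 99.91). cyp7a1 (chromosome 2, 22150134 to 22152797), the rate-limiting enzyme of bile acid synthesis in the liver, was at 34.3 ± 2.01 FPKM in the control and 364 ± 6.14 in the Cavendish library. nr0b2b, a repressor of bile acid synthesis genes, was at 9.22 ± 2.01 and 0.664 ± 0.502, and slc10a2, the bile acid uptake carrier, was 2.09-fold higher. Among 36 brush border hydrolases and amino acid carriers, 2 were called higher and 2 lower, at a median of -0.25 (-0.51 to -0.20 over the alternatives, percentile 0.16); the alkaline phosphatase alpi.2 was at 153 ± 7.08 and 58.5 ± 3.2.

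Among 39 genes of carotenoid and retinoid handling, 3 were called higher and 2 lower in the Cavendish library, and the median of -0.10 lay within the range of random lists (percentile 13.9). The carotenoid-cleaving enzyme bco1 was at 90.1 ± 5.1 FPKM in the control and 63.2 ± 3.77 in the Cavendish library, and its paralog bco1l at 85.5 ± 4.84 and 119 ± 5.89. scarb1, a receptor through which carotenoids enter enterocytes, was at 57.2 ± 3.39 and 92.7 ± 4.22, below the 2-fold threshold. The retinol-binding protein rbp2b was 2.64-fold higher, while its abundant paralog rbp2a was at 7457 ± 61.2 and 6181 ± 52.2. rbp5 and rdh12 were 3.97-fold and 2.92-fold higher.

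Inflammation and acute phase genes were higher in the Cavendish library, with 18 of 44 called higher and 1 lower (median 0.84, above all random lists; 0.41 with a pseudocount of 5 and 0.46 without a minimum FPKM). The list holds complement and acute phase genes that the liver makes, and the liver list was higher in this library too (median 0.84, 10 of 29 called). duox (chromosome 25, 31958911 to 32018990) and duox2 carry dual oxidases, which release hydrogen peroxide at epithelial surfaces. duox was at 0.922 ± 0.269 FPKM in the control and 24.2 ± 1.49 in the Cavendish library, and duox2 at 0.548 ± 0.239 and 21.3 ± 1.39. cxcl8b.1, a chemokine that draws neutrophils, was at 38.5 ± 4.17 and 231 ± 9.50. The cytokine il13 was 18.3-fold higher. Of 18 neutrophil and granulocyte genes, 6 were called higher (median 0.51, percentile 99.98; 0.24 with TPM), among them mmp9, 7.54-fold higher, and rnasel2, 17.9-fold higher. cpa5, in the same list, is also in the exocrine pancreas list. Macrophage genes had a median of -0.02, with 0 of 18 called higher and 3 lower, and mfap4 was at 324 ± 16.8 and 17.2 ± 2.4 FPKM. Interferon response genes had a median of -0.27 (-0.42 to -0.16 over the alternatives, percentile 0.01), with 3 of 42 called higher and 2 lower. Lymphocyte genes had a median of 0.02 (percentile 38.8), with 3 of 29 called higher.

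Of 43 antioxidant genes 4 were called higher, led by the glutathione transferase gstp2 at 0.330 ± 0.330 and 24.8 ± 2.69 FPKM, and the median of 0.14 turned below 0 under the other scalings (-0.02 for the deposited FPKM, -0.16 for TPM, -0.01 for TPM without pancreas and mitochondrial genes). Xenobiotic metabolism genes had 5 of 90 called higher and 13 lower (median -0.17, -0.41 to -0.07 over the alternatives, percentile 0.09), with cyp2k6 10.0-fold higher and the sulfotransferase sult3st3 6.08-fold lower. Of 34 genes of endoplasmic reticulum stress, 0 were called higher and 3 lower, among them the chaperone hspa5, at 210.2 ± 4.61 and 101 ± 2.91, and the median was -0.18 (percentile 5.02). Heat shock and immediate early genes had 5 of 38 called higher (median 0.39, percentile 99.99; 0.15 with TPM and 0.18 with a pseudocount of 5).

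Transcripts of other tissues were higher in the Cavendish library too. Of 28 exocrine pancreas genes 22 were called higher and 0 lower, with a median of 1.57, and the amylase amy2a was at 503 ± 20.1 FPKM in the control and 2769 ± 115 in the Cavendish library. Of 9 endocrine pancreas genes 6 were called higher (median 2.4, 1.57 without a minimum FPKM), and insulin (ins) was at 233 ± 17.6 and 2307 ± 105. Smooth muscle and fibroblast genes, which mark the gut wall, had 18 of 29 called higher (median 1.32, 0.80 with a pseudocount of 5), with desmb 5.77-fold and dcn 4.07-fold higher. Of 29 liver genes 10 were called higher (median 0.84) and of 11 erythrocyte genes 7 (median 1.11, 0.57 without a minimum FPKM). The medians of these 5 lists lay above all random lists. Enteroendocrine genes had 6 of 27 called higher and 1 lower (median 0.56, 0.35 with TPM and 0.32 with a pseudocount of 5), and 4 genes of that list are also endocrine pancreas genes. Enterocyte genes had a median of 0.17 that turned to -0.10 under TPM scaling, with 5 of 28 called higher and 1 lower.

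The excess of higher over lower calls depends on the scaling. Of the calls 77.5% were higher, against 66.9% with the deposited FPKM, 53.4% with TPM and 68.5% with TPM without pancreas and mitochondrial genes. TPM scaling moved the median log2 ratio of all measured genes from 0.02 to -0.19, and so set 517 genes higher and 452 lower.

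The same question was asked of the Fe'i diet. In the Fe'i library, genes of lysosome-rich enterocytes, which take up and degrade protein in the posterior intestine, were higher than in the control library, as were 4 of 16 iron handling genes and the heme-degrading hmox1a. Liver and egg genes were higher as well. Cholesterol synthesis and exocrine pancreas genes had medians near 0. cyp26a1 again had the lowest ratio among called genes with a gene name, at 2.65 ± 0.736 FPKM against 74.0 ± 4.37 in the control (log2 ratio -4.36, counting SE 0.15). In all, 693 genes were called higher and 252 lower.

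Of 22 genes of lysosome-rich enterocytes 13 were called higher in the Fe'i library and 0 lower (median 1.15, above all random lists). ctsl.1 (chromosome 17, 27456804 to 27461321), a lysosomal protease, was at 1507 ± 61.8 FPKM in the control and 5631 ± 215 in the Fe'i library, and the protease ctsbb was at 741 ± 42.2 and 2640.1 ± 116. The endocytic receptor cubn was at 11.5 ± 0.469 and 43.3 ± 1.07, and its partner amn at 25.4 ± 1.94 and 92.8 ± 4.28. Enterocyte genes as a whole had a median of 0.08 (percentile 91.0), with 1 of 28 called. The part of the intestine taken is not given, so whether the libraries held unlike amounts of posterior intestine was not tested.

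**Figure D2:**
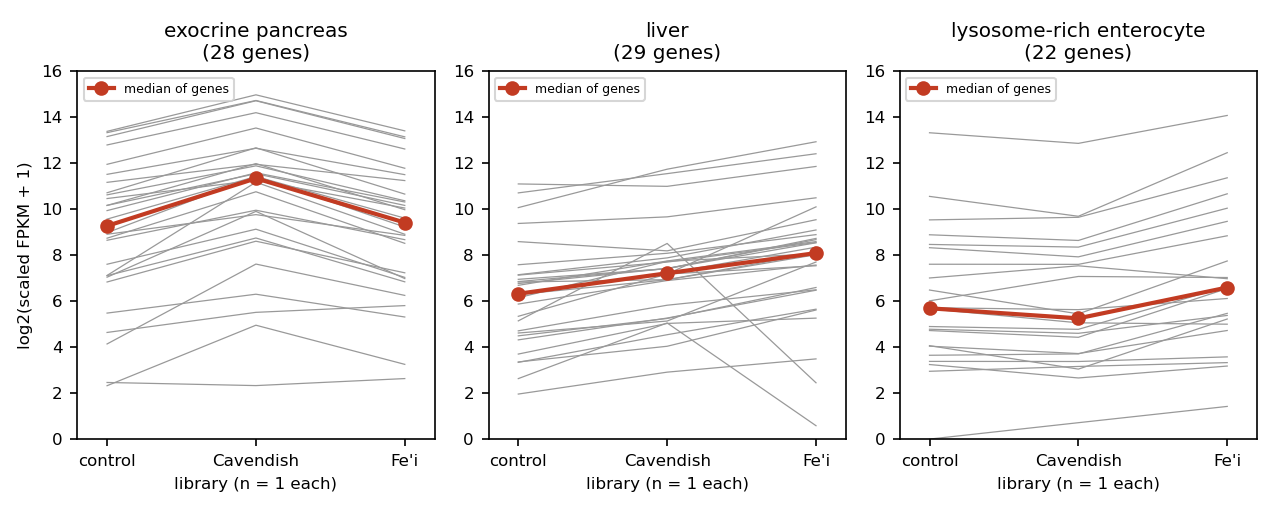
Lines join the log2(scaled FPKM + 1) of each measured gene of the exocrine pancreas (28 genes), liver (29 genes) and lysosome-rich enterocyte (22 genes) lists across the control, Cavendish and Fe'i libraries, 1 library each; points are the median over genes. The exocrine pancreas median was highest in the Cavendish library and the liver and lysosome-rich enterocyte medians in the Fe'i library, and the liver lines that drop furthest in the Fe'i library are cyp7a1 and 1 of 2 genes named hp.

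Of 16 iron handling genes 4 were called higher in the Fe'i library and 0 lower (median 0.27, percentile 98.3), and the median fell back among the random lists with a pseudocount of 0.1 or a minimum of 5 FPKM (lowest percentile 96.7). The iron exporter slc40a1 was at 42.1 ± 1.56 FPKM in the control and 113 ± 2.98 in the Fe'i library, and the iron importer slc11a2 at 38.5 ± 2.37 and 86.9 ± 4.11. hmox1a (chromosome 3, 26011482 to 26017831), which degrades heme, was at 5.53 ± 1.03 and 66.8 ± 4.87, a 10.4-fold difference. tfa, transferrin, is made in the liver and was 3.26-fold higher alongside the other liver genes. Erythrocyte genes had 7 of 11 called higher (median 1.49, 0.67 with a pseudocount of 5 and 0.51 without a minimum FPKM), with hbaa1 at 53.7 ± 5.27 and 227 ± 12.7. Of 43 antioxidant genes 5 were called higher (median 0.04, percentile 86.3), with gstp2 at 50.8 ± 4.79 FPKM against 0.330 ± 0.330.

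Liver genes had 25 of 29 called higher and 2 lower in the Fe'i library (median 1.78, above all random lists). hpx, hemopexin, was at 79.0 ± 4.18 FPKM in the control and 1098 ± 46.6 in the Fe'i library, and the liver fatty acid binding protein fabp10a was 7.29-fold higher. The 2 called lower were cyp7a1, at 34.3 ± 2.01 and 4.46 ± 0.839, and hp on chromosome 7, at 5.19 ± 0.973 and 0.497 ± 0.603. A second gene named hp, on chromosome 8, was at 113 ± 7.93 and 272 ± 14.2. Of 44 inflammation and acute phase genes 8 were called higher (median -0.01, percentile 46.2), and the leading ones, cfb and c3a.1, c3a.2 and c3a.3, encode complement proteins that the liver makes. Egg and germ cell genes had 17 of 20 called higher, where 14 of the 20 reached 1 FPKM in this library alone (median 1.94, above all random lists; 2.99 and 0.89 with a pseudocount of 0.1 and 5, and 0.94 without a minimum FPKM), with the egg envelope genes zp3a.2 at 0.390 ± 0.260 and 11.2 ± 1.64 and zp3a.1 at 1.81 ± 0.576 and 15.5 ± 1.98. Skeletal muscle genes had 10 of 14 called lower at low levels (median -1.15; -2.00 and -0.42 with a pseudocount of 0.1 and 5, and -0.51 without a minimum FPKM), with mylpfa at 6.18 ± 1.06 and 1.24 ± 0.560.

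Lipid absorption genes in the Fe'i library had 7 of 39 called higher, 8 lower and a median of -0.49, below all random lists. apoa4a was at 108 ± 7.66 FPKM and apoeb at 295 ± 12.4 in the Fe'i library, 6.52-fold and 5.26-fold below the control, while apoa2, also made in the liver, was 4.12-fold higher. Cholesterol synthesis genes had 0 of 29 called (median 0.15, percentile 98.1; 0.01 with TPM and 0.02 with the deposited FPKM, and back among the random lists under 3 of 8 alternatives), with hmgcra at 25.1 ± 1.72. In fatty acid synthesis, thrsp was 23.8-fold higher and me1 4.30-fold lower, the only calls among 21 genes, and the median was -0.20 (percentile 1.92), back among the random lists under 3 of 8 alternatives (percentile up to 40.2). Fatty acid oxidation genes had 1 of 31 called higher and 2 lower (median -0.03). Of 34 sugar uptake and glycolysis genes 5 were called higher (median -0.07, percentile 23.5), with ldhbb 5.68-fold higher. In gluconeogenesis (13 genes, median 0.20) pck1 was 4.21-fold lower and g6pca.1 3.24-fold higher. Among 18 bile acid genes 5 were called higher and 2 lower (median 0.35, 0.22 to 0.37 over the alternatives, percentile 99.8). fgf19, an intestinal hormone that bile acids induce, was at 1.38 ± 0.676 and 10.4 ± 2.02, and nr0b2b at 0.293 ± 0.415 in the Fe'i library. Brush border hydrolases and amino acid carriers had a median of -0.05 (percentile 37.5).

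Carotenoid and retinoid genes had 2 of 39 called higher and 1 lower in the Fe'i library, with a median of -0.10 (percentile 7.36). bco1 was at 80.2 ± 5.03 FPKM, bco1l at 68.5 ± 4.56 and scarb1 at 34.9 ± 3.08, none past the threshold. rbp2b was 3.87-fold higher and the plasma retinol carrier rbp4, a liver product, 2.17-fold higher. Of the other fixed genes, stra6 was at 12.0 ± 1.09 in the control, 9.81 ± 0.963 in the Cavendish and 12.1 ± 1.27 in the Fe'i library, and lrata at 6.97 ± 1.25, 3.70 ± 0.854 and 4.40 ± 1.17. dhrs3a was at 2.01 ± 0.536, 2.00 ± 0.498 and 1.54 ± 0.538. bco2b stayed under 1 FPKM in all 3 libraries, as did lratb.1.

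Interferon response genes had 4 of 42 called higher and 0 lower (median 0.23, 0.09 to 0.26 over the alternatives, percentile 99.92), with isg15 at 27.6 ± 2.53 and 91.7 ± 5.34 FPKM. Macrophage genes had a median of -0.38 (percentile 0.03) and lymphocyte genes of -0.36 (below all random lists, -0.48 to -0.13 over the alternatives), with 2 of 18 called higher and 2 lower in the first and 0 of 29 in the second. Neutrophil genes had 3 of 18 called higher, with rnasel2 38.1-fold and mpx 2.36-fold higher. Xenobiotic genes had 6 of 90 called higher and 8 lower (median -0.14, -0.31 to -0.08 over the alternatives, percentile 0.23), with cyp2p8 12.5-fold lower. Exocrine pancreas genes had a median of -0.03 (percentile 52.4) with 3 of 28 called higher, and endocrine pancreas genes a median of 1.14 (0.66 without a minimum FPKM) with 5 of 9 called higher. Smooth muscle and fibroblast genes had 1 of 29 called (median 0.16). Of the calls against control 73.3% were higher, against 65.7% with the deposited FPKM, 64.7% with TPM and 68.5% with TPM without pancreas and mitochondrial genes.

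**Figure D3:**
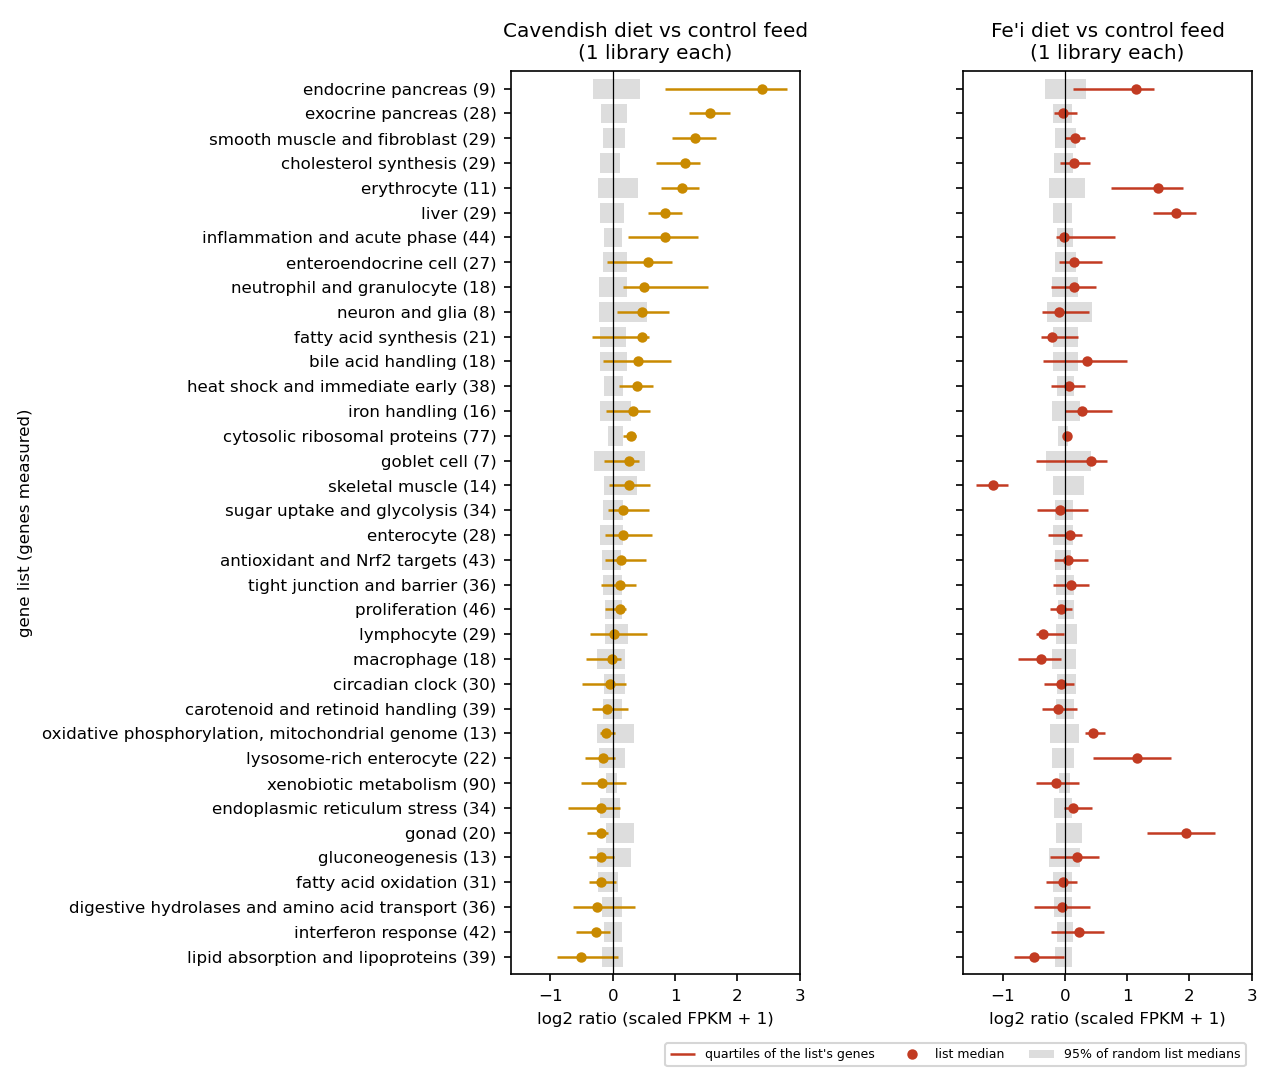
Median log2 ratio (points) and quartiles (lines) of the measured genes of 36 lists in the Cavendish and the Fe'i library, each against the control library; grey bars hold 95% of the medians of random lists matched on expression. Cholesterol synthesis stood at 1.15 in the Cavendish and 0.15 in the Fe'i library, and lysosome-rich enterocytes at -0.15 and 1.15; the antioxidant, enterocyte and sugar medians (Cavendish) and the endoplasmic reticulum stress median (Fe'i) turn below 0 under TPM scaling.

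The third comparison sets the banana kinds against each other at the same share of pulp. The Fe'i library had 594 genes called higher and 633 lower than the Cavendish library. Cholesterol synthesis genes were lower, with 12 of 29 called (median -0.98), and hmgcra was at 93.9 ± 4.34 FPKM in the Cavendish and 25.1 ± 1.72 in the Fe'i library. Inflammation genes had 3 of 44 called higher and 16 lower (median -0.51; -0.20 with a pseudocount of 5, -0.14 without a minimum FPKM and -0.25 with a minimum of 5), with duox 13.5-fold, cxcl8b.1 6.88-fold and saa 4.67-fold lower. Exocrine pancreas genes had 23 of 28 called lower (median -1.57), endocrine pancreas genes 5 of 9 and smooth muscle and fibroblast genes 18 of 29 (median -1.12). The endocrine median was -1.11, and the medians of these 5 lists lay below all random lists.

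Higher in the Fe'i than in the Cavendish library were lysosome-rich enterocyte genes, with 13 of 22 called (median 1.23), liver genes, with 15 of 29 called higher and 2 lower (median 1.09), and egg and germ cell genes, with 17 of 20 (median 2.2; 3.84 and 0.89 with a pseudocount of 0.1 and 5, and 0.93 without a minimum FPKM). Interferon response genes had 11 of 42 called higher and 1 lower (median 0.45, 0.28 to 0.54 over the alternatives), among them rsad2 at 8.72 ± 1.07 and 42.2 ± 2.93 FPKM and ifit14 at 24.8 ± 2.01 and 103 ± 5.08. Genes of endoplasmic reticulum stress had 8 of 34 called higher and 1 lower (median 0.34), with hspa5 at 101 ± 2.91 and 301 ± 6.40. The medians of these 5 lists lay above all random lists. cyp7a1 was 66.8-fold lower and crp6, a C-reactive protein gene, 44.3-fold lower. Carotenoid and retinoid genes had 0 of 39 called higher and 3 lower (median 0.02, percentile 55.5): rdh12, rbp5 and scarb1, the last at 92.7 ± 4.22 and 34.9 ± 3.08. Of these calls 48.4% were higher, 48.3% with the deposited FPKM, 57.7% with TPM and 51.3% with TPM without pancreas and mitochondrial genes.

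The design also asks what both banana diets share against control. Both libraries had 177 genes called higher and 70 called lower, and 19 genes were higher in one and lower in the other. With TPM scaling the shared calls were 113 higher and 122 lower, so the excess of higher ones depends on the scaling. Among those lower in both were cyp26a1, apoa4a, apoeb, me1 and the clock repressors nr1d1 and ciarta; among those higher in both were thrsp, gstp2, rnasel2, rbp2b and slc10a2. Independent lists would share 26.2 higher and 4.56 lower of 12815 genes testable in both. Unchanged libraries against 1 shared control shared 4.37 higher and 3.43 lower on average with counting error only, and 164 and 179 with the spread between libraries added. With that spread they averaged 612 genes called higher and 617 lower in the Cavendish, and 616 and 637 in the Fe'i comparison. Observed calls were 799 and 232, and 693 and 252. Simulated higher calls ranged from 552 to 665 in the Cavendish and from 561 to 688 in the Fe'i comparison. Lower calls ranged from 563 to 668 and from 569 to 692. Observed higher calls lay above these ranges and observed lower calls below them. The spread, which includes any effect of the kind of banana, thus gives many calls but not the observed counts. The shared numbers therefore rest on unlike totals. The log2 ratios correlated across genes, which are not independent replicates, at r = 0.393 (covariance 0.156). The simulated values were r = 0.475 (covariance 0.0454) with counting error only and 0.492 (0.207) with the added spread, so the covariance differed from the simulated one by 0.11 or by -0.0509. The lowest simulated r with the added spread was 0.464, above the observed r. With the added spread, simulated sharing ranged from 125 to 198 higher and from 140 to 213 lower genes. The 177 genes higher in both lay within the first range. The 70 genes lower in both lay below the second, but the simulated libraries had far more lower calls to share. For lower genes the comparison therefore decides nothing. With 1 control library the controls cannot be split, and part or all of the sharing may come from that library.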

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

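The tests of pancreatic tissue and of hp and cyp7a1 were chosen after the results were seen, while the tests on a second liver list and a second oocyte list were written before the values of those genes were looked at.

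Some results went opposite ways in the Cavendish and the Fe'i library when each was set against the control library, and none of these differences between the diets was tested, since each diet has 1 library. The fatty acid synthesis list had a median log2 ratio of 0.46 in the Cavendish and -0.20 in the Fe'i library, the latter between -0.33 and -0.01 over the alternative settings and back among the random lists under 3 of 8, at percentiles up to 40.2. The egg and germ cell list was at -0.18 and 1.94 (0.89 to 2.99 over the alternatives), and the interferon response list at -0.27 and 0.23. Of single genes, 19 were called higher in one banana library and lower in the other. Unchanged libraries with 1 shared control and the spread between libraries gave 7.31 such genes on average and 18 at most in 100 simulations. The spread was drawn for each gene on its own, so genes that move together would widen this range, and it sets no bound.

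Of these 19 genes, 12 are named by the rule. Higher in the Fe'i than in the Cavendish library, with the control library between them, were cyp2k22, a cytochrome P450 (log2 ratio 3.56), the fatty acid binding protein fabp7a (3.26), the opioid peptide precursor penkb (2.55), and the endocytic genes dab2 (2.3) and lrp2b (2.18). fabp7a was at 145 ± 10.1 FPKM in the control, 30.6 ± 3.75 in the Cavendish and 302 ± 18.4 in the Fe'i library. Lower in the Fe'i library were cyp7a1 (-6.06), the C-reactive protein genes crp7 (-5.49) and crp6 (-5.47), hp on chromosome 7 (-4.47) and the skeletal muscle genes mylpfa (-2.71), acta1b (-2.45) and acta1a (-2.38). The muscle genes were at no more than 13.7 FPKM in any library.

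cyp7a1 and hp are also in the liver list, and other genes of organs that lie against the intestine had the following values. Insulin was at 233 ± 17.6 FPKM in the control and 2307 ± 105 in the Cavendish library. The second liver list had 42 measured genes, of which 38 had a log2 ratio above 0.5 in the Fe'i and 27 in the Cavendish library, 41 were at 1 FPKM or more in the control library, and 1 was also in another list. Its most abundant member, mbl2, was at 749.6 ± 25.1 in the control and 561 ± 20.5 in the Fe'i library. The second oocyte list had 41 symbols and 12 measured genes, of which 10 were above 0.5 in the Fe'i and 2 in the Cavendish library, and 4 were at 1 FPKM or more in the control library. Levels of egg genes were low, with zp3a.1 at 15.5 ± 1.98 in the Fe'i library. vtg2, a yolk protein gene of the female liver picked after its values were seen, was at 2193 ± 9.81 in the control, 2040.3 ± 8.75 in the Cavendish and 3719 ± 14.8 in the Fe'i library.

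More liver tissue left on the intestine may account for the higher liver genes of the Fe'i library, where 90.5% of the second liver list were above 0.5. Alone it would not give the lower mbl2, nor the lower cyp7a1 and hp on chromosome 7, of which the nearer to 0 had a log2 ratio of -2.05. These genes were picked because they were lower, so they do not test the explanation, and a second hp gene, on chromosome 8, was higher there. The higher exocrine pancreas genes of the Cavendish library stay open: all 10 of the most abundant were above 0.5, but these are genes of the list that raised the question, and ptf1a, a transcription factor of the same list, was at 4.51 ± 1.31 FPKM in the control and 4.02 ± 1.15 in the Cavendish library. The endocrine pancreas median was 2.4 there and 1.14 in the Fe'i library, where the exocrine median was -0.03, so the lists need not move together, 4 of the 9 endocrine genes are also enteroendocrine genes, and more pancreatic tissue cannot be told apart from higher expression of digestive enzymes. Counting chance among low genes does not give the higher egg genes of the Fe'i library, where zp2.3 had a log2 ratio of 3.19 (counting SE 0.18), 17 of 20 were called higher and, although 14 of the 20 reached 1 FPKM in that library alone, the list median without a minimum FPKM (0.94) also lay above all random lists; 83.3% of the second oocyte list were above 0.5, but 8 of its 12 measured genes were measured through that library alone, so ovary tissue cannot be told apart from expression outside the ovary. Differences within the liver or pancreas by diet, sex or individual fish were not tested.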

How the results depend on the processing

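The alternative without organ and tissue genes was chosen after seeing the data; all others were planned. Of 461 comparisons of genes named by the rule, 0 called ones changed direction, but log2 ratios moved by more than their counting interval in 202 with a pseudocount of 5, 196 with TPM, 107 with the deposited FPKM, 80 with a pseudocount of 0.1 and 73 with TPM without pancreas and mitochondrial genes. List medians numbered 108, and by the same measure 80 moved with TPM, 47 with the deposited FPKM, 39 with TPM without those genes, 35 with a pseudocount of 5, 30 without a minimum FPKM, 28 with a minimum of 5 and 15 with a pseudocount of 0.1. In all, 59 of 108 list medians lay outside the range that holds 95% of random lists, 50 of them under every alternative. The 9 others, with the number of 8 alternatives that ended it, were antioxidant (6), enterocyte (6), iron handling (4) and sugar uptake (3) in Cavendish against control, cholesterol synthesis (3), fatty acid synthesis (3) and iron handling (2) in Fe'i against control, and erythrocyte (1) and gluconeogenesis (1) in Fe'i against Cavendish. Of 27 such medians of at least 0.5 in size, 14 moved by over 1.5 times under some alternative; 12 are given with the results, and in Fe'i against Cavendish the erythrocyte median went from 0.51 to 0.04 without a minimum FPKM, and the skeletal muscle median from -1.44 to between -2.47 and -0.19. Of 32 smaller ones 27 did so. Those not given elsewhere ranged as follows: in Cavendish against control, egg and germ cell -0.80 to -0.06 and iron handling 0.11 to 0.40; in Fe'i against control, iron handling 0.17 to 0.36; in Fe'i against Cavendish, ribosomal -0.26 to -0.13, enteroendocrine -0.57 to -0.28, fatty acid synthesis -0.51 to -0.23, gluconeogenesis 0.08 to 0.52, heat shock -0.27 to -0.15 and proliferation -0.23 to -0.09. The correlation of the log2 ratios of both banana diets stayed between 0.393 and 0.423. Counts of calls follow, with Cavendish against control first, then Fe'i against control, then Fe'i against Cavendish. TPM scaling gave 517 higher and 452 lower in the first, and 113 higher and 122 lower in both banana libraries. Without pancreas and mitochondrial genes in the TPM sum, 359 were lower in the first and 106 lower in both. A pseudocount of 0.1, which lets low genes pass, gave 1279 higher in the first, 395 lower in the second and 1014 lower in the third, with 297 higher and 113 lower in both. A pseudocount of 5, which holds them back, gave 280 higher and 95 lower, 333 and 79, and 277 and 225, with 67 and 30 in both. A minimum of 5 FPKM gave 491 higher in the first, 160 lower in the second and 393 lower in the third. A log2 ratio of 2 gave 128 higher and 43 lower, 163 and 40, and 137 and 101, with 20 and 17 in both. The other settings stayed within 1.5 times, and removing the minimum of 1 FPKM moved no count, so it tests nothing for counts. Leaving out organ and tissue genes gave 733 higher and 232 lower, 635 and 240, and 561 and 575, with 155 and 70 in both.

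Of the 59 list medians, 4 changed sign under a scaling. In Cavendish against control, the antioxidant median became -0.0188 with the deposited FPKM, -0.157 with TPM and -0.0126 with TPM without pancreas and mitochondrial genes. The enterocyte median became -0.0968 and the sugar uptake median -0.0360 with TPM. In Fe'i against control, the endoplasmic reticulum stress median became -8.31e-05 with the deposited FPKM and -0.00719 with TPM. A scaling moves all log2 ratios of a comparison almost alike, and these medians lay near 0. The Fe'i library was the shallowest, with 115 effective fragments for a median measured gene against 180 in the Cavendish library. Genes of few FPKM rest on few fragments, such as most egg genes in the control and skeletal muscle genes in the Fe'i library.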

Other observations

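Of the tests in this part, those of the commercial feed share and of liver RNA were chosen after the results were seen, and those of pancreatic RNA and of retinoic acid signalling before.

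Of 30 clock genes 0 were called higher and 2 lower in each banana library, with medians of -0.04 in the Cavendish and -0.06 in the Fe'i library. Both were repressors: nr1d1 was at 6.80 ± 0.723 FPKM in the control, 1.55 ± 0.319 in the Cavendish and 2.3 ± 0.491 in the Fe'i library, and ciarta at 7.17 ± 0.787, 1.76 ± 0.360 and 3.08 ± 0.595. The hour of sampling is not given in the sources used here. Of 46 proliferation genes 0 were called in either (medians 0.11 and -0.07). In Fe'i against Cavendish their median was -0.18 (percentile 0.29), outside the range of random lists under all 8 alternatives, with 1 called lower, rrm2 on chromosome 20, a subunit of ribonucleotide reductase, at 19.5 ± 1.64 FPKM in the Cavendish and 7.46 ± 1.33 in the Fe'i library. Cytosolic ribosomal protein genes (77) had a median of 0.29 in the Cavendish library (percentile 99.99; 0.02 with TPM, and 0.16 with the deposited FPKM or TPM without pancreas and mitochondrial genes) and 0.03 in the Fe'i library. Mitochondrially encoded genes (13) were at -0.10 and 0.46, the latter at percentile 99.7, with mt-nd3 at 1638 ± 90.3 FPKM in the control and 4425 ± 216 in the Fe'i library.

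Barrier and secretory genes held single genes that stood apart. Of 36 tight junction and barrier genes 3 were called higher and 1 lower in the Cavendish library and 3 higher and 0 lower in the Fe'i library, at medians of 0.12 and 0.10. The claudin cldnb was 6.13-fold higher in the Cavendish library, and cldnd, also in the egg and germ cell list, was at 6.20 ± 1.82 FPKM in the Fe'i library. Goblet cell genes (7) had 0 called in both, at 0.27 and 0.41, and the mucus-folding gene agr2 was at 304 ± 15.1, 374 ± 17.8 and 163 ± 9.89. Enteroendocrine genes had a median of 0.14 in the Fe'i library, with 4 of 27 called higher and 1 lower. Neuron and glia genes (8) were at 0.47 and -0.09, with 1 called higher and 1 lower in the Cavendish library and 1 higher in the Fe'i library. Heat shock and immediate early genes (38) had 1 called higher in the Fe'i library (median 0.07), and endoplasmic reticulum stress genes (34) likewise (median 0.13, below 0 with TPM). In the Cavendish library, iron handling genes had 1 of 16 called higher (median 0.32), skeletal muscle genes 3 of 14 (0.26) and lysosome-rich enterocyte genes 1 of 22 higher and 2 lower (-0.15). Egg and germ cell genes had 0 of 20 called there (-0.18).

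A few genes were listed at 0 in some libraries and high in another, and 18 genes were listed at 0 in at least 1 library and at 20 FPKM or more in another. The galectin gene lgals9l6 (chromosome 15, 30987414 to 31000275) was at 278 ± 14.2 FPKM in the Cavendish and 0.568 ± 0.546 in the Fe'i library and listed at 0 in the control library. The chemokine gene ccl39a.10 was at 108 ± 69.9 in the Fe'i library and listed at 0 in the others, and the claudin cldn18 was at 13.2 ± 1.67 in the Cavendish library and listed at 0 in the others. The first 2 of these belong to families of closely similar genes, so their values are uncertain.

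Cholesterol synthesis genes were higher than control in the Cavendish library, with 18 calls, and had 0 calls in the Fe'i library. Both banana feeds held the same share of commercial feed, and the Fe'i median was 0.15, so the smaller share of that feed did not go with higher genes in both. The pulps differ and each diet has 1 library, so an effect of that share is not excluded. Liver RNA was highest in the Fe'i library, where these genes were lower than in the Cavendish library (median -0.98), so they did not follow the amount of liver RNA. Whether the liver expressed them differently in each library was not tested. The liver gene cyp7a1 was also highest in the Cavendish library, at 364 ± 6.14 FPKM against 34.3 ± 2.01 in the control and 4.46 ± 0.839 in the Fe'i library. More pancreatic RNA remains open: 0 of the 29 genes had a log2 ratio above 2.70, the 90th percentile of exocrine pancreas genes, but that bound rests partly on elastase genes whose values are uncertain, and hmgcra at 2.23 lay above the upper quartile of the exocrine list (1.88) and above each of its 10 most abundant genes, so the count decides nothing. An answer of the intestine to Cavendish pulp is another candidate explanation, untested without replicates or sorted cells.

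The retinoic acid hydroxylase gene cyp26a1 was lower in both banana libraries, and retinoic acid is known to induce it. If signalling by retinoic acid were lower in both, at least 4 of 7 other genes (dhrs3a, isx, cyp26b1, rarga, bco1, bco1l and scarb1) were to move past 0.5 in a direction fixed in advance in both libraries, and 0 did. Of these 5 were measured, and only measured genes could count, so 4 of 5 had to pass. dhrs3a and rarga were near 2 FPKM or less, so the result rests mainly on bco1, bco1l and scarb1. Lower signalling is therefore not excluded. The counting SE of the cyp26a1 log2 ratios was 0.14 and 0.15, so counting error does not give the difference, and a high value in the fish of the 1 control library was not tested.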
